A study of Mus musculus with 64 samples.

How the data were processed

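The assay was ATAC-seq, in which the transposase Tn5 cuts accessible DNA and inserts sequencing adapters there. Per the labels' protocols, mouse embryonic fibroblasts (MEF) were infected with retroviruses, cultured in iCD1 or embryonic stem cell medium, and collected for libraries that were sequenced on a NextSeq 500. Bowtie2, SAMtools, bedtools and bcl2fastq are named without versions, and mm10 is given as the genome build, per the submitters' processing notes. The peak caller, its threshold and any shift of reads for the Tn5 cut are not given in the sources used here.

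Each of the 64 samples came with 1 deposited list of genomic regions, so the regions were listed per sample and not only on pooled samples. Every listed region was 700 bp wide, as measured on the files, and many coordinates recurred exactly between lists. The deposited files carry a score column that is 0 throughout, so no height, p-value or read count was at hand: a region is either listed (called open below) or not listed. Read depth is therefore unknown. A region that is not listed may be closed, or may lie under a threshold that depends on depth. The number of listed regions (92603 to 227681, median 154904) is at best an indirect trace of depth per library. Over 60 samples it went only weakly with the percent of always-open regions, defined below, that were open (r = 0.251). In 10 lists, all from GFP-sorted cells, between 1162 and 4688 regions were written more than once and were counted once.

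The lists held 817713 distinct regions. Overlapping regions (at least 1 bp) were merged into 814615, and the 648103 present in at least 2 lists formed the catalogue, of which 99.5% were 700 bp wide. A catalogue region was open in a sample if a listed region of that sample overlapped it. Regions open in both ESC samples and in neither MEF sample were called ESC-specific (39795), the converse MEF-specific (65128), and those open in all 4 of these samples always open (31363). Each other sample was summarised as the percent of each class that it had open, with the always-open class as a technical control. Wilson 95% intervals were computed for samples without replicates and cover counting error only.

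Samples were grouped by their labels. Percentages with time were tested by a two-sided permutation test of Pearson's r and Spearman's rho with 100000 resamples. The 8 groups at day 1 form a full factorial of the factors O, S and K; each main effect was the mean difference over the 4 combinations of the other factors, tested by a two-sided exact permutation within those strata and adjusted by Benjamini-Hochberg over 6 tests. Regions gained or lost with a factor were open in at least 7 of 8 samples on one side and at most 1 of 8 on the other. The cJun comparison was stratified by day (days 1, 3 and 7), with regions called at 5 of 6 against at most 1 of 6. The GFP comparison was also stratified by day, with regions called when open in every sample of one side and at most 1 of the other. Comparisons of 2 against 2 samples cannot give an exact p below 0.333. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

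Genes were taken from GENCODE M21 on GRCm38, the assembly of mm10, whose chromosome lengths contained all regions. Coordinates are 1-based. Lists of pluripotency, fibroblast and mesenchymal, epithelial, AP-1 family, Hox, extraembryonic, neural, muscle, endothelial, haematopoietic, keratinocyte, SIN3-HDAC complex, and cell cycle and housekeeping genes were written before the data were examined. For each list, regions of a class within 50 kb of a transcription start site (TSS) were counted for each gene, so a region near several list genes counted for each of them, and compared with 10000 random lists matched on the number of catalogue regions near the gene. As an addition, gene order was rotated along the genome so that clustered genes stayed clustered. The genes named in the report come from the 4 with most changed regions in each list and comparison, ties by alphabet and only with at least 1; not all of these are printed. For each set of changed regions, counts are also given for Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Cdh1, Epcam, Thy1, Twist2, Col1a1, Jun and Sap30 whatever their values. Coordinates belong to the changed region nearest the TSS, and distances to a TSS were taken from the midpoint of the region. Consensus sequences of 18 transcription factor families were searched on both strands of the central 500 bp, and shares were compared by Fisher's exact test with Benjamini-Hochberg adjustment over 90 tests. Regions are not independent replicates, so these tests describe the region sets and not the spread between cultures.

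The code was tested on simulated data. In 400 regions changed in a simulation of the S comparison at day 1, 92% were recovered and 155 unchanged regions of 648103 were counted as well. In the cJun simulation 92.25% of 400 were recovered and 1441 unchanged regions were counted. Changed regions were simulated as nearly always open on one side and nearly never on the other. The calls of each sample were otherwise shuffled over the catalogue on their own, without the likeness between real samples. These counts are therefore not error rates for the real data. Simulated samples without a shift gave p under 0.05 in 4% (S), 4.6% (cJun) and 5.2% (GFP) of 500 draws. Alternatives covered the overlap rule, 500-bp tiles, regions found in 1 list only, classes that include iPS cells, scaling by always-open regions, leaving out each replicate, a replicate block, stricter counts of samples, other gene windows, GC matching and distal regions only. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.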

Results

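Chromatin accessibility was profiled by ATAC-seq in 64 mouse samples that follow fibroblasts on their way to induced pluripotent stem (iPS) cells, in a series concerned with the order in which chromatin opens and closes during reprogramming. The end points were MEF and embryonic stem cells (ESCs), with 2 samples each, and 2 samples of iPS cells. OSK stands for the retroviral factor combination of O, S and K, the usual initials of Oct4, Sox2 and Klf4. OSK cells were sampled at days 0, 1, 3, 5 and 7. At day 1 every subset of the factors was sampled, with the fluorescent protein DsRed as the virus without a factor. Further groups received OSK with cJun, an AP-1 transcription factor, or OSK with DR, an abbreviation that the labels do not spell out, and were sampled at days 0, 1, 3 and 7. GFP-positive and GFP-negative cells were sampled at days 3 and 7, and mES-OSK cells at day 7. Each of these groups had 2 samples except the GFP-negative cells of day 3, with 4. At days 3 and 7, OSK cells with a scrambled hairpin and with either of 2 hairpins against Sap30 had 1 sample each. Replicates shared a median of 49.2% of their listed regions (Jaccard index, up to 65.5%, and as low as 23% in GFP-negative and 23.7% in GFP-positive cells of day 3 and 30.4% in OSK cells of day 5), and no 2 lists were close to identical.

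MEF and ESCs differed at regions near genes that mark each cell type. All 35 genes of the pluripotency list had at least 1 ESC-specific region within 50 kb, 245 region-to-gene assignments in all and 3.73 times the mean of random lists (adjusted permutation p = 0.0039, from random gene lists). The most were near Fbxo15 (17), an early reporter gene of the pluripotent state, Tet2 (16), which oxidises methylated cytosine, and the neighbouring genes Dppa4 (15) and Dppa2 (13). Nanog had 12, Zfp42 had 11, Cdh1 had 8 and Sap30 had 5, whereas Pou5f1, Sox2, Esrrb and Jun had 2 each, Klf4 and Epcam 1 each, and Thy1, Twist2 and Col1a1 none. The ESC-specific region of Nanog on chromosome 6, 122707144 to 122707843, lay over its TSS in the untranslated region. That of Zfp42 on chromosome 8, 43306828 to 43307527, had its midpoint in intergenic sequence 197 bp from the TSS, so its 700 bp covered the TSS as well. By contrast, the promoters of Pou5f1 and Sox2 had an open region within 1 kb of the TSS in 2 of 2 MEF samples and in 2 of 2 ESC samples.

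MEF-specific regions lay near 37 of the 38 genes of the fibroblast and mesenchymal list, with 310 assignments, 2.65 times the random mean (adjusted permutation p = 0.0039). Thbs1, which encodes a matrix glycoprotein, had 20, and the collagen genes Col5a1, Col1a1 and Col1a2 had 18, 15 and 13. Twist2 had 7 and Thy1, a surface marker of fibroblasts, had 6. Jun had 12, Klf4 5, Sap30 4, Pou5f1, Sox2 and Cdh1 2 each and Esrrb 1, while Nanog, Zfp42 and Epcam had none. The nearest to Col5a1, on chromosome 2, 27887817 to 27888516, was intronic, and the nearest to Thbs1, on chromosome 2, 118112908 to 118113607, overlapped a coding exon. The Hox list, whose genes set position along the body axis, had MEF-specific regions near 38 of 39 genes (323 assignments to 55 distinct regions, 2.20 times the random mean, adjusted permutation p = 0.0039, and 0.0364 with gene order rotated) and few ESC-specific ones (27 assignments, ratio 0.349, adjusted permutation p = 0.0039). The latter call ended when gene order was rotated, with an adjusted permutation p = 0.147. The pluripotency list had few MEF-specific regions (69, ratio 0.609, adjusted permutation p = 0.0218), a call that also ended under rotation (adjusted permutation p = 0.0741) and in a 10 kb window (adjusted permutation p = 0.0936). The other lists passed for neither class, with adjusted permutation p of at least 0.339, although the AP-1 family passed for MEF-specific regions in a 10 kb window (ratio 2.30, adjusted permutation p = 0.0374). Their ratios of ESC-specific and then MEF-specific regions were 1.2 and 0.804 for epithelial genes, 0.811 and 1.43 for the AP-1 family, 1.54 and 1.04 for extraembryonic genes, 0.785 and 0.715 for neural, 1.02 and 0.910 for muscle, 1.16 and 1.34 for endothelial, 1.04 and 1.15 for haematopoietic, 0.630 and 0.855 for keratinocyte, 1.24 and 1.02 for SIN3-HDAC complex genes, and 1.40 and 0.898 for cell cycle and housekeeping genes.

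The classes also differed in the DNA sequences they hold. The AP-1 consensus was present in 36.9% of MEF-specific and 8.70% of ESC-specific regions (log2 odds ratio -2.62, 95% interval -2.67 to -2.56). RUNX matches were likewise commoner in MEF-specific regions (12.0 against 5.70%), as were TEAD matches (18.7 against 12.5%). ESC-specific regions more often held the composite OCT-SOX sequence (1.07 against 0.0706%, log2 odds ratio 3.93), the KLF sequence (7.73 against 2.49%) and the SOX sequence (16.1 against 9.21%). Both classes were mostly distal, with 5.75% of ESC-specific and 4.24% of MEF-specific regions within 1 kb of a TSS, compared with 46.6% of always-open regions.

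From day 0 of the OSK time course, the mean percent of MEF-specific regions open fell most between days 0 and 1. That of ESC-specific regions rose in smaller steps up to day 7. MEF-specific regions were open at 65.3% ± 2.54 (SD, n = 2) on day 0, 37.1% ± 1.46 on day 1, 30.1% ± 7.47 on day 3, 24.7% ± 0.609 on day 5 and 23.1% ± 0.377 on day 7. ESC-specific regions were open at 21% ± 2.54, 25.7% ± 4.69, 28.4% ± 6.10, 30.4% ± 3.70 and 34.7% ± 2.35 on the same days. The DsRed samples of day 1 had 68.7% ± 5.59 of MEF-specific and 9.12% ± 1.25 of ESC-specific regions open. Day 0 is thus not an unchanged baseline. ESC-specific regions were 11.9 points more open in OSK samples of day 0 than with DsRed, in groups that did not overlap. The difference in MEF-specific regions was -3.40 points, in groups that overlapped. In iPS cells, 76.2% of ESC-specific regions were open on average, with 62.9 and 89.5% in the separate samples.

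The closing of MEF-specific regions with day gave Pearson's r = -0.821 (permutation p = 0.00183, adjusted over 2 tests 0.00366) and Spearman's rho = -0.960 (permutation p = 0.00011). Without the 2 samples farthest from the median day, r was -0.842 (exact permutation p = 0.00873, n = 8). The opening of ESC-specific regions gave r = 0.823 (permutation p = 0.00573, adjusted 0.00573) and rho = 0.862 (permutation p = 0.00301). Without the 2 farthest samples, r was 0.703 (exact permutation p = 0.0599, n = 8). The call was thus lost, though fewer samples and a shorter range of days may be enough for that. Always-open regions gave r = -0.357 (permutation p = 0.304), and without the 2 farthest samples r = -0.697 (exact permutation p = 0.0631) and rho = -0.781 (exact permutation p = 0.0349, n = 8).

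**Figure D1:**
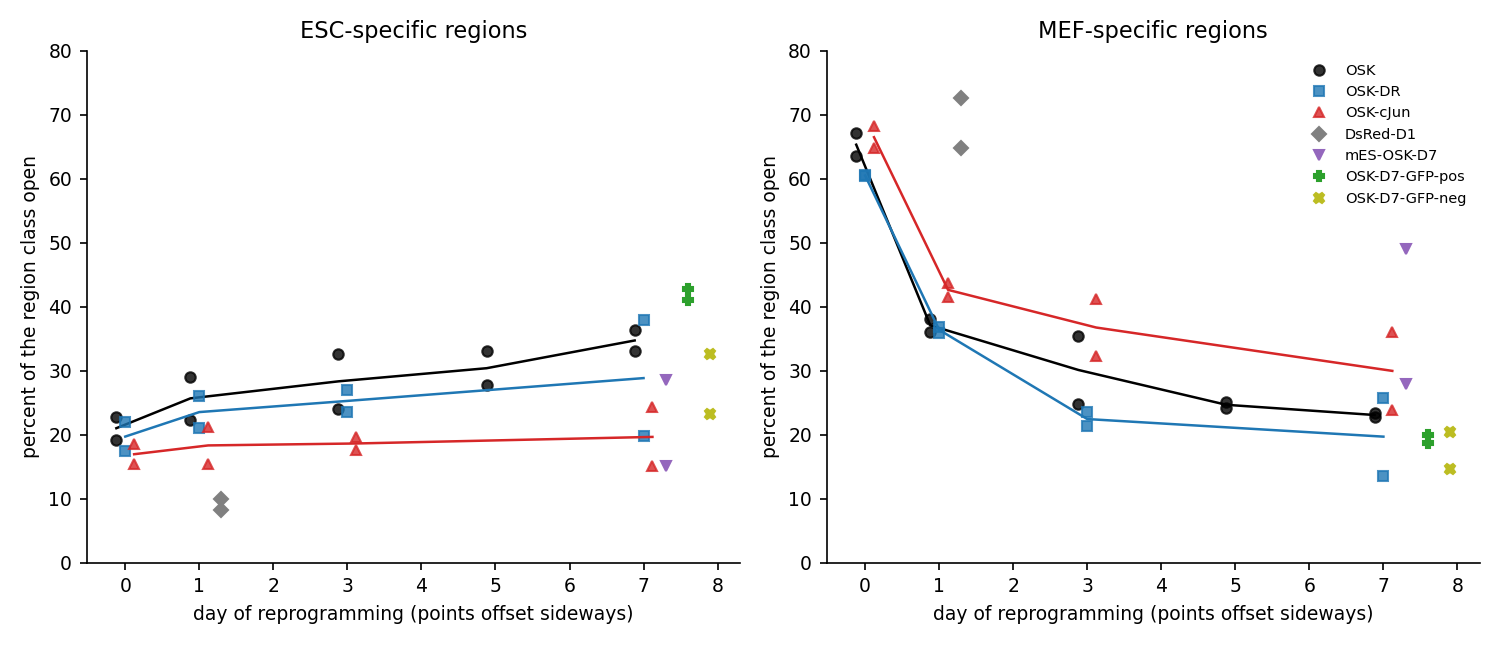
Percent of ESC-specific (left) and MEF-specific (right) regions open in each sample against day, with lines through group means for OSK, OSK-DR and OSK-cJun and single points for DsRed, mES-OSK and GFP-sorted samples. In OSK, MEF-specific regions had a mean of 65.3% on day 0 and 37.1% on day 1, while ESC-specific regions went from 21% on day 0 to 34.7% on day 7.

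The pluripotency genes followed different courses. Of the 16 ESC-specific regions near Tet2, 1.5 ± 0.707 (SD, n = 2) were open in DsRed samples, 7 ± 1.41 in OSK cells on day 0 and 13 ± 0 on day 7. Of the 12 near Nanog, 1 ± 1.41 was open on day 0, 4 ± 0 on day 1 and 9 ± 1.41 on day 7, and the region over the Nanog TSS was open in 0 of 2 samples on days 0 and 1, 1 of 2 on days 3 and 5, and 2 of 2 on day 7. Near Cdh1, which encodes the epithelial adhesion protein E-cadherin, 0 of 8 regions were open in either DsRed sample, 3 ± 0 on day 0 and 5.5 ± 0.707 on day 7. Near Dppa4, 0 of 15 regions were open in either OSK sample on day 7, and likewise 0 of 13 near Dppa2. In iPS cells the counts were 11.5 ± 3.54 for Dppa4 and 10 ± 4.24 for Dppa2. These differences between genes were not tested.

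Regions near fibroblast genes also followed different courses. Of 20 MEF-specific regions near Thbs1, 16.5 ± 0.707 (n = 2) were open on day 0, 6 ± 1.41 on day 1 and 2.5 ± 2.12 on day 7. Of 18 near Col5a1, 15 ± 0 were open on day 1 and 3.5 ± 2.12 on day 7. Near Col1a1, 10.5 ± 0.707 of 15 were open on day 7 and 3.5 ± 2.12 in iPS cells. Near Hoxb5, 13 ± 1.41 of 17 regions were open on day 7 and 4.5 ± 2.12 in iPS cells. Over all genes of a list, 27.2% ± 5.49 of the 309 distinct MEF-specific regions near fibroblast genes were open on day 7, as against 58.2% ± 15.4 of the 55 near Hox genes and 60.1% ± 7.17 of the 69 near AP-1 family genes such as Jun and Fos. The difference between lists was not tested.

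**Figure D2:**
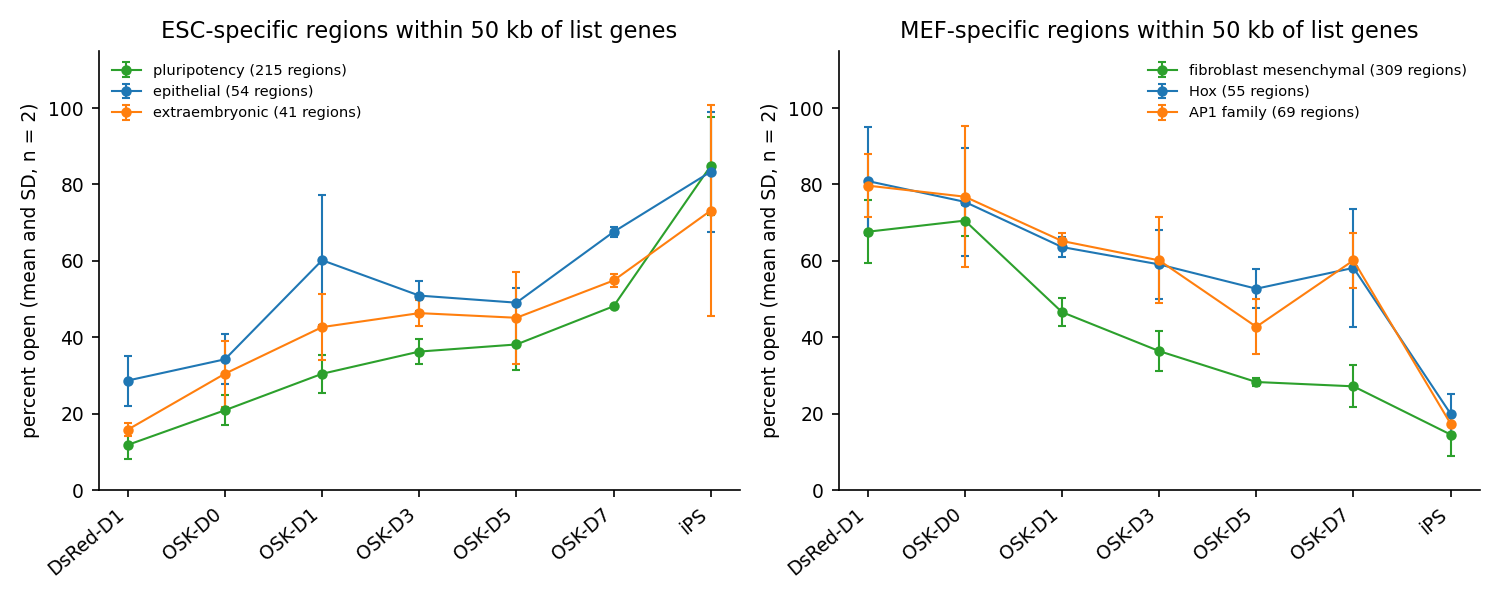
Percent open (mean and SD, n = 2 samples per group) of ESC-specific regions near pluripotency, epithelial and extraembryonic genes (left) and of MEF-specific regions near fibroblast, Hox and AP-1 family genes (right), from DsRed through the OSK days to iPS cells. ESC-specific regions near pluripotency genes went from 20.9% on day 0 to 48.1% on day 7.

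When each region was dated by the day from which it was open or closed in both replicates on every sampled day through day 7, most ESC-specific regions were not open in both samples of day 7. Of 39795 ESC-specific regions, 1951 (4.90%) were open from day 0, 851 (2.14%) from day 1, 830 (2.09%) from day 3, 955 (2.40%) from day 5 and 4642 (11.7%) on day 7, and 30566 (76.8%) were not open in both samples of day 7. The latter include 5050 (12.7% of the class) that both samples of an earlier day had open. Of 65128 MEF-specific regions, 8355 (12.8%) were closed from day 0, 12451 (19.1%) from day 1, 5437 (8.35%) from day 3, 6703 (10.3%) from day 5 and 10800 (16.6%) on day 7. The remaining 21382 (32.8%) were open in at least 1 sample of day 7. Both DsRed samples, which had no factor, had only 38946 of the 65128 MEF-specific regions open. Regions dated as closed from an early day may therefore include some that were not listed without factors either. A region counted on day 7 had only to meet the rule on that day, so its share is not comparable with those of earlier days. The rule needs both replicates: in replicate 1 alone, 66.9% of ESC-specific regions were not open on day 7, with 21.1% of the class open on an earlier day only, and in replicate 2 alone these shares were 63.6 and 25.7%.

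**Figure D3:**
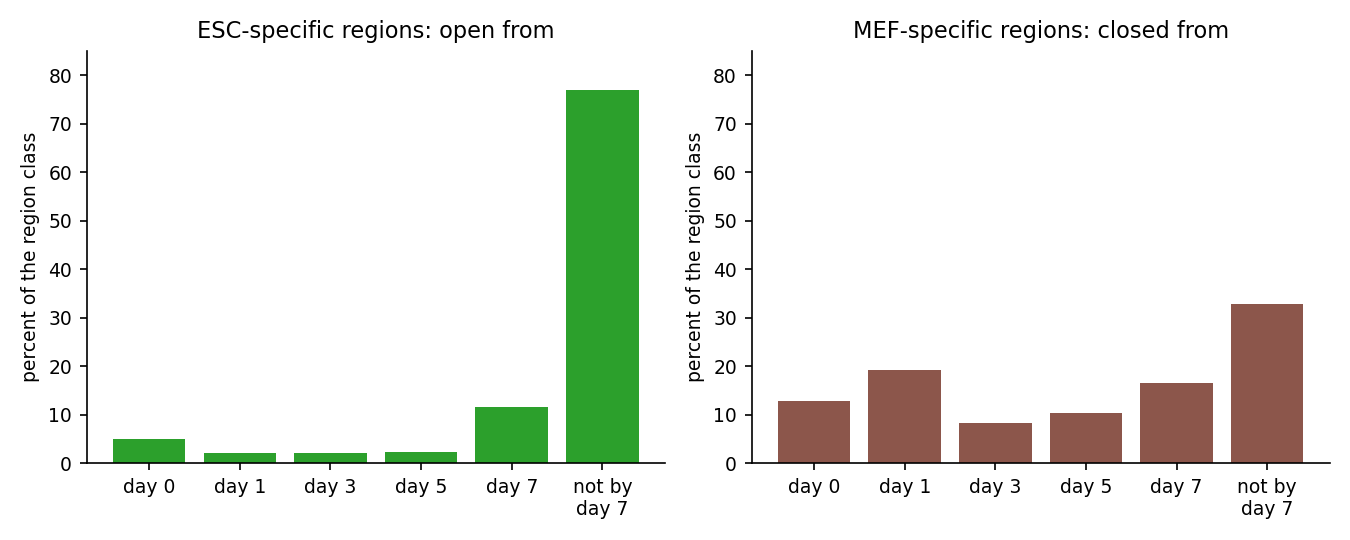
Percent of ESC-specific regions by the day from which they were open in both OSK samples (left) and of MEF-specific regions by the day from which they were closed in both (right), with the rest in the last bar. The last bars stand at 76.8% and 32.8%.

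At day 1, each factor was compared over the 8 samples with it and the 8 without it, which asks what each contributes to opening and closing. ESC-specific regions were more open with each factor: by 6.63 percentage points with S (adjusted exact permutation p = 0.00463), 7.05 with K (adjusted exact permutation p = 0.00463) and 3.62 with O (adjusted exact permutation p = 0.0167), each in 4 of 4 combinations of the other factors. MEF-specific regions were less open with S (-11.2 points, adjusted exact permutation p = 0.00926) and with K (-11.3 points, adjusted exact permutation p = 0.00617), again in 4 of 4 combinations. The change with O was -4.38 points (adjusted exact permutation p = 0.116), lower in 3 of 4 combinations. It passed the threshold when K-D1 replicate 1 was left out (-5.71, adjusted exact permutation p = 0.0148) and when percentages were scaled by always-open regions (-4.73, adjusted exact permutation p = 0.0401).

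Among single factors, K-D1 samples had 12.5% ± 2.33 (SD, n = 2) of ESC-specific regions open, S 10.4% ± 0.0942 and O 9.55% ± 2.97, beside 9.12% ± 1.25 with DsRed. The pairs SK, OS and OK had 20.3% ± 0.178, 16.4% ± 0.139 and 15.2% ± 0.714, and OSK had 25.7% ± 4.69. MEF-specific regions were open at 45.1% ± 5.35 with SK and 37.1% ± 1.46 with OSK. In 6 tests of whether a factor acted differently in the presence of another, the adjusted exact permutation p was at least 0.704, in a family of 10 that also held tests of the cJun and GFP effects between days. These tests reassigned the factor's labels, so its own effect widens the null, and they cannot show that effects add up. On ESC-specific regions, S added 9.16 points with K and 4.09 without. There O added 5.66 with S and 1.59 without, and 4.06 with K and 3.19 without. On MEF-specific regions the change with O was smaller with K (-2.84) than without (-5.93). Always-open regions differed with S by -1.69 points (exact permutation p = 0.216), with K by -1.27 (exact permutation p = 0.344) and with O by -0.234 (exact permutation p = 0.855).

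**Figure D4:**
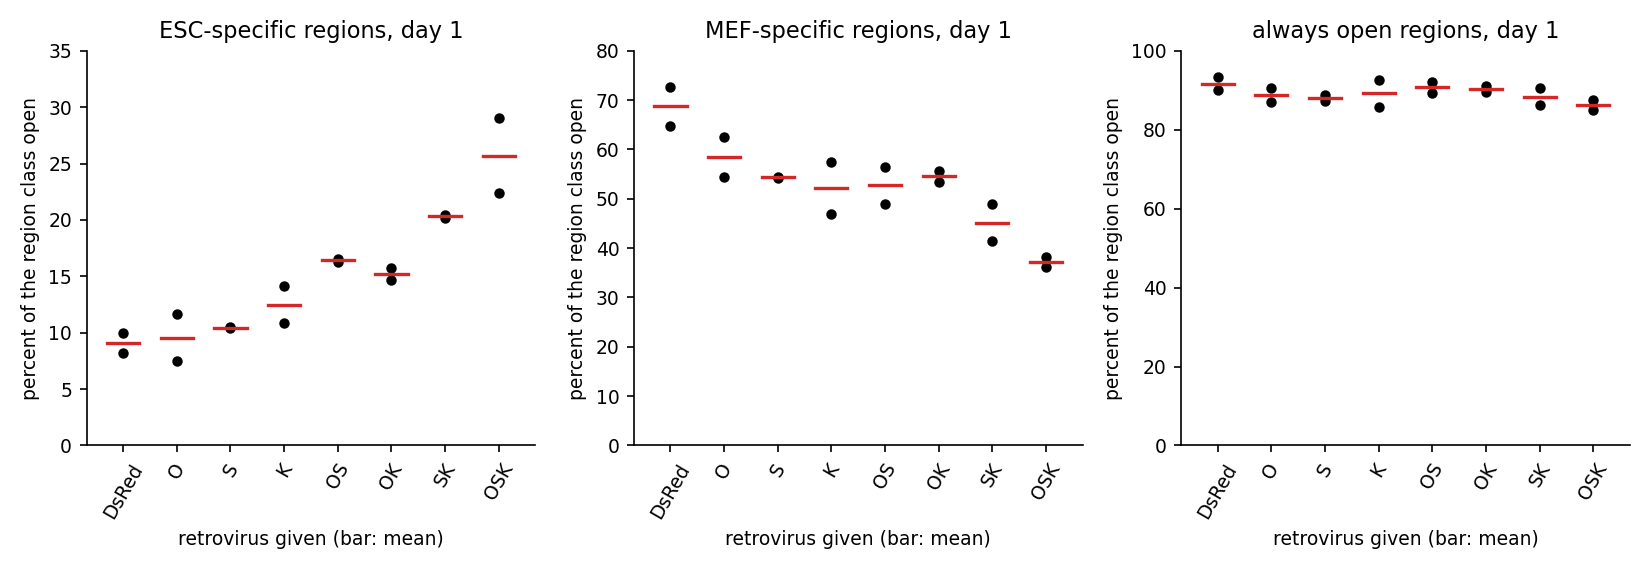
Percent of ESC-specific, MEF-specific and always-open regions open in each of the 16 samples of day 1 by the virus given, with bars at the means (n = 2). ESC-specific regions ranged from a mean of 9.12% with DsRed to 25.7% with OSK.

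Regions gained with each factor held its binding sequence more often than other regions did, although most of them had no match. S gained 10076 regions and lost 3637, K gained 3113 and lost 1400, and O gained 1499 and lost 205. With 1 sample left out the rule is easier to meet, so no count can fall. The count gained with O then reached 2283 (without OK-D1 replicate 1) and that gained with K 4929 (without OSK-D1 replicate 1). The count lost with K reached 2140 (without O-D1 replicate 1) and that lost with O 439 (without OK-D1 replicate 1). The OCT sequence was found in 19.2% of regions gained with O, against 3.61% of all other regions (log2 odds ratio 2.67, 95% interval 2.48 to 2.86). In the same regions AP-1 matches were commoner than OCT matches (27.8%, against 17.0% of other regions, log2 odds ratio 0.91, and 0.04 against regions open in as many day 1 samples), and CEBP matches were in 17.3% against 8.64% (1.15). The SOX sequence was in 25.3% of those gained with S against 11.2% (1.43, 1.37 to 1.5), and the KLF sequence in 17.3% of those gained with K against 4.25% (2.24, 2.10 to 2.37). Regions lost with a factor held the AP-1 sequence in 41.0% (O), 48.4% (S) and 49.1% (K) of cases, compared with 17.0% of all regions, and 42.4, 41.7 and 56.1% of them were MEF-specific. Most regions gained with O (60.2%), S (65.6%) and K (50.5%) were open in no MEF and no ESC sample, and 6.74, 7.47 and 13.9% were ESC-specific. AP-1 matches in regions gained with S and with K lay above all other regions (log2 odds ratios 0.52 and 0.45) but below regions open in as many day 1 samples (-0.43 and -0.44), so that direction depends on the background.

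Regions gained with O included 2 near Fbxo15, the nearest on chromosome 18, 84945598 to 84946579, in an intron of the gene, and 1 in an intron of Gdf3, a growth factor gene expressed in pluripotent cells, on chromosome 6, 122608154 to 122608853. With S, 1 region was gained 12.5 kb from the TSS of Sox2, on chromosome 3, 34637559 to 34638258, in an intron of the non-coding gene Sox2ot, 2 near Tet2 and 2 near Dppa2. S also gained 3 regions near the fibronectin gene Fn1 and 3 near Acta2, and the fibroblast list as a whole had 2.18 times the random mean (adjusted permutation p = 0.0801). With K, 4 regions were gained near Tet2, 3 near each of the neighbouring keratin genes Krt8 and Krt18 of simple epithelia, and 1 near Cdh1, on chromosome 8, 106572165 to 106572864, in intergenic sequence 30.8 kb from the TSS. As lists, pluripotency genes did not pass with O (ratio 1.88), S (1.14) or K (0.987), each with an adjusted permutation p = 1, nor did epithelial genes with K (ratio 1.84, adjusted permutation p = 0.788). K gained 1 region near Hox genes, which was fewer than in random lists (ratio 0.0836, adjusted permutation p = 0.0214, and 0.817 with gene order rotated). With S, regions were lost near Dcn and Col5a2, both matrix genes, and 2 near Klf4. As lists, fibroblast genes had 8 assignments of regions lost with S (ratio 1.33) and pluripotency genes 7 (ratio 1.24), and neither passed. Among genes named whatever their values, Epcam, Thy1 and Col1a1 each gained 1 region with S and Klf4, Esrrb and Sap30 each gained 1 with K, and Sap30 lost 1 with S. Nanog, Pou5f1, Zfp42, Twist2 and Jun had no region gained or lost with any factor, and none of the genes so named had one with O.

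**Figure D5:**
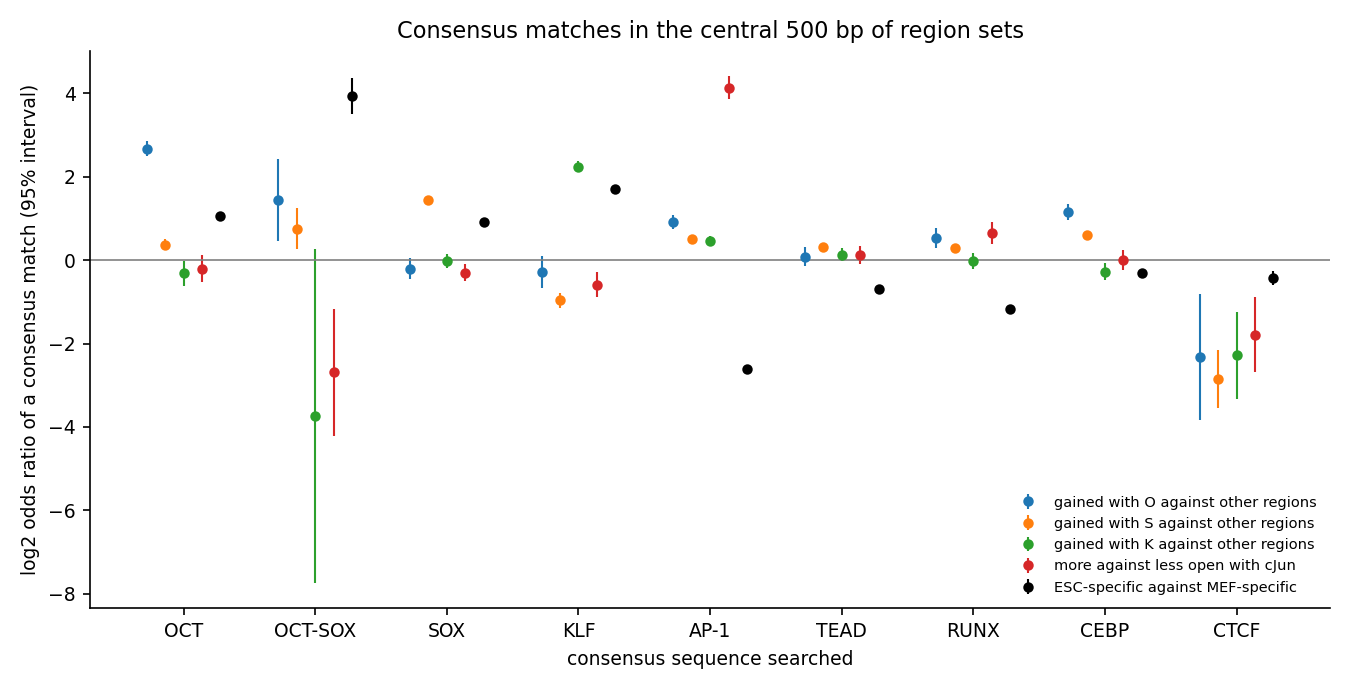
Log2 odds ratio, with 95% interval, of a consensus match in the central 500 bp of each region set against its comparison set, by consensus sequence. OCT stands at 2.67 in regions gained with O, SOX at 1.43 with S, KLF at 2.24 with K and AP-1 at 4.13 in regions more open with cJun.

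The coding exons of the factors were also examined, since retroviral copies of a gene can add reads to its exons. A region of Klf4 on chromosome 4, 55527946 to 55528645, that holds 173 coding bases was open in 2 of 2 samples of K, OK, SK and OSK at day 1 and in 0 of 2 samples of DsRed, O, S and OS. It was open in 0 of 2 ESC samples, 1 of 2 MEF and 1 of 2 iPS samples. This region counts among those gained with K near Klf4, and accessibility of the endogenous gene cannot be read from it. Other exon regions were open in GFP-sorted samples alone: one of Sox2 (chromosome 3, 34650745 to 34651444, 628 coding bases) and one of Klf4 (chromosome 4, 55531400 to 55532099, 126 coding bases) in all 10, and one of Jun (chromosome 4, 95051121 to 95051820, 151 coding bases) in all but OSK-D3-GFP-neg, where 3 of 4 had it. These are among the 67268 catalogue regions listed in sorted samples only, and the Jun region was open in 0 of 2 samples of each OSK-cJun group, so they are not read as signs of the viral copies. Those of Pou5f1 were open in every sample.

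Cells that received cJun with OSK had more of the MEF-specific regions open than OSK-DR cells. Over days 1, 3 and 7, MEF-specific regions were open at 36.5% with cJun and 26.2% with DR, a difference of 10.3 points that went the same way on all 3 days (exact permutation p = 0.0185, adjusted over 2 tests 0.037, n = 6 against 6). By day the means were 42.6 and 36.4% on day 1, 36.8 and 22.5% on day 3, and 30.0 and 19.7% on day 7. On day 0, outside this test, they were 66.5 and 60.5%, a difference of 5.99 points between groups that did not overlap, as against 6.25 on day 1. ESC-specific regions were open at 18.9% with cJun and 25.9% with DR, a difference of -7.02 points, lower on all 3 days (exact permutation p = 0.0556, adjusted 0.0556). Always-open regions differed by -0.904 points (exact permutation p = 0.713). The MEF-specific call ended without OSK-cJun-D7 replicate 2 (8.26, exact permutation p = 0.0556), without OSK-DR-D7 replicate 1 (8.24, exact permutation p = 0.0556) and without day 7 (10.3, exact permutation p = 0.0556, the smallest that design allows). The ESC-specific difference was -4.00 without OSK-DR-D7 replicate 2 (exact permutation p = 0.167), and its p went below 0.05 under 8 alternatives, among them -10.0 without OSK-DR-D7 replicate 1 (exact permutation p = 0.0185) and -7.98 when scaled by always-open regions (exact permutation p = 0.0278).

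At single regions, 4585 were more open with cJun and 2459 less open. The 1441 counted among unchanged regions in simulation are no error rate for these counts, since each sample's calls were shuffled on their own. Other splits of the real samples within days gave a median of 1351 regions, more and less open together, and up to 4725, against 7044 in the real one. With 1 sample left out, which eases the rule so that no count can fall, up to 9545 regions were more open (without OSK-DR-D1 replicate 2). Up to 5379 were less open (without OSK-DR-D7 replicate 1). Of the regions more open, 34.2% were MEF-specific, and of those less open, 21.7% were ESC-specific. The AP-1 sequence was present in 47.9% of regions more open with cJun and 4.96% of those less open (log2 odds ratio 4.13, 95% interval 3.86 to 4.41). Regions more open with cJun included 2 near each of Thy1, Col3a1, Col1a2, Col5a1 and Postn, which is a matrix protein gene, and 1 in an intron of Twist2 on chromosome 1, 91825214 to 91825913. The fibroblast list as a whole had 17 assignments, 1.90 times the random mean, and did not pass (adjusted permutation p = 0.291). Regions less open with cJun included 2 near Tet2, 2 near Fbxo15, 1 near Zfp42 and 1 near Cdh1, on chromosome 8, 106599459 to 106600158, in intergenic sequence 3.54 kb from the TSS, with 12 assignments over the pluripotency list (ratio 2.06, adjusted permutation p = 0.291). Klf4 had 1 region more open with cJun. Jun, Nanog, Pou5f1, Sox2, Esrrb, Epcam, Col1a1 and Sap30 had no region of either kind.

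GFP-positive and GFP-negative cells were compared within days 3 and 7. On day 7, ESC-specific regions were open at 41.9% ± 1.2 (SD, n = 2) in GFP-positive and 27.9% ± 6.59 in GFP-negative cells, and on day 3 at 28.8% ± 8.40 (n = 2) and 28.0% ± 2.10 (n = 4). Near Fbxo15, 10.5 ± 0.707 of 17 ESC-specific regions were open in GFP-positive and 5 ± 2.83 in GFP-negative cells on day 7. Over both days, the difference in ESC-specific regions was 7.42 points (exact permutation p = 0.133, adjusted over 2 tests 0.267) and that in MEF-specific regions -2.04 points (exact permutation p = 0.456). The latter differed in direction by day, with -5.89 points on day 3 and 1.80 on day 7 (19.4% in GFP-positive and 17.6% in GFP-negative cells). On day 3 the GFP-positive samples had 71.6% ± 8.84 of always-open regions open and the GFP-negative ones 83.0% ± 10.7. The unadjusted p of the ESC-specific difference went below the threshold when percentages were divided by those of always-open regions (10.3, exact permutation p = 0.0333) and without OSK-D3-GFP-pos replicate 1 (10.4, exact permutation p = 0.0333), which also turned the MEF-specific difference to 0.0194.

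Between the sorted samples of day 7 alone, 12808 regions were open in both GFP-positive and neither GFP-negative sample, and 6729 the reverse. Mixed pairs of these samples gave up to 10387. Over both days, other splits were not counted. Regions open in every GFP-positive sample and at most 1 GFP-negative sample numbered 782, of which 23% were ESC-specific. Those open in every GFP-negative and at most 1 GFP-positive sample numbered 903, of which 20.7% were MEF-specific. The former included 1 in an intron of Ocln, a tight junction gene, on chromosome 13, 100551102 to 100551801, and 1 near the claudin gene Cldn6. The latter included 1 near each of Col1a2, Tgfbr2 and Zeb2, the last in an untranslated region of this mesenchymal regulator on chromosome 2, 45112807 to 45113506. Of the genes named whatever their values, Sap30 had 1 region in the GFP-positive set, and Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Cdh1, Epcam, Thy1, Twist2, Col1a1 and Jun had none in either. No gene list passed for either set: the epithelial list had 6 assignments in the GFP-positive set (ratio 2.13, adjusted permutation p = 0.642), the pluripotency list had 0 there (adjusted permutation p = 0.642) and the fibroblast list 3 in the GFP-negative set (ratio 1.12, adjusted permutation p = 1).

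The mES-OSK cells of day 7 were set beside OSK cells of day 7. ESC-specific regions were open at 21.8% and 34.7%, and MEF-specific regions at 38.5% and 23.1%. Near Col5a1, 11.5 ± 0.707 (SD, n = 2) of 18 MEF-specific regions were open in mES-OSK and 3.5 ± 2.12 in OSK cells, and near Nanog 3 ± 1.41 and 9 ± 1.41 of 12 ESC-specific regions. The differences of -12.9 and 15.4 points each had an exact permutation p of 0.333, the smallest that 2 against 2 samples allow. Without mES-OSK-D7 replicate 1 the differences were -6.22 and 25.9 points, and without replicate 2 they were -19.6 and 4.90. Always-open regions differed by -0.697 points.

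Cells with hairpins against Sap30, a subunit of the SIN3-HDAC corepressor, had a less ESC-like profile than scrambled control cells on day 7. ESC-specific regions were open at 40% (Wilson 95% interval 39.5 to 40.5) with the scrambled hairpin, 29.9% (29.4 to 30.3) with hairpin 1 and 24.8% (24.4 to 25.2) with hairpin 2. MEF-specific regions were open at 22.7% (22.4 to 23), 30.7% (30.3 to 31) and 39.8% (39.4 to 40.1). On day 3 the differences from the scrambled hairpin were -2.44 and -4.20 points for ESC-specific and -0.166 and 3.59 for MEF-specific regions. With MEF-specific regions limited to those that both DsRed samples also had open, the mean difference over both hairpins and days was 11.3 points, as against 7.10 with all of them. Each value is from 1 sample, so the differences have no replicate check, and the extent of knockdown is not measured by accessibility.

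On day 7, 28099 regions were open with the scrambled hairpin and closed with both Sap30 hairpins, and 17776 were the reverse. On day 3, when the classes differed less, the counts were 28905 and 11990, so the first count was as large without the class differences of day 7. Among MEF-specific regions, 5943 were open with both Sap30 hairpins only, 7711 with hairpin 2 only and 2900 with hairpin 1 only. Among ESC-specific regions, 4688 were closed with both Sap30 hairpins, 2704 with hairpin 2 alone and 1527 with hairpin 1 alone. The regions open only with the scrambled hairpin included 5 regions near Nanog, the nearest on chromosome 6, 122708722 to 122709421, in an intron of the gene, 6 near Cdh1, 9 near Tet2, 7 near Sap30, 4 near Pou5f1, 3 near each of Esrrb, Zfp42, Col1a1 and Jun, 2 near Epcam, 1 near Sox2 and 1 near Twist2, and none near Klf4 and Thy1. Those open only with both Sap30 hairpins included 6 near Col5a1, 5 near Prrx1, 4 near Jun, 3 near Thy1, 3 near Col1a1, 2 near Cdh1 and 1 near each of Pou5f1, Nanog, Esrrb, Epcam and Twist2, and none near Sox2, Klf4, Zfp42 and Sap30. On day 3, the former set had 6 near Col1a1, 4 near each of Esrrb, Cdh1 and Sap30, 3 near Sox2 and Twist2, 2 near Nanog and Jun, 1 near Pou5f1, Klf4, Epcam and Thy1, and none near Zfp42, and the latter 4 near Cdh1 and Thy1, 3 near Twist2, 2 near Esrrb, Col1a1 and Jun, and none near the others. The AP-1 sequence was present in 42.5% of regions open only with the Sap30 hairpins and in 9.34% of those open only with the scrambled one. The matching lists did not pass: for regions open only with the scrambled hairpin, pluripotency genes had a ratio of 1.35 (adjusted permutation p = 0.104) and epithelial genes 1.05 (adjusted permutation p = 1), and for the reverse, fibroblast genes had 1.48 (adjusted permutation p = 0.104). Among pluripotency genes the regions open only with the Sap30 hairpins were few (21 assignments, ratio 0.481, adjusted permutation p = 0.0191, and 0.320 with gene order rotated), and near Hox genes so were those open only with the scrambled hairpin (82, ratio 0.561, adjusted permutation p = 0.0143, and 0.870 with gene order rotated; on day 3, 57, ratio 0.486, adjusted permutation p = 0.0143, and 0.817 rotated).

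Finally, iPS cells were compared with ESCs. The 2 iPS samples differed from each other, with 62.9 and 89.5% of ESC-specific and 15.9 and 11.9% of MEF-specific regions open. In all, 13107 regions were open in both iPS samples and in neither ESC sample, and 3807 the reverse, while mixed pairs of 1 iPS and 1 ESC sample against the others gave up to 12324. Leaving out a sample eases this rule, so the counts can only rise, and a rise does not show that they depend on a single sample. When iPS replicate 1 was left out, 40439 regions were open in iPS and in neither ESC sample, and 64293 when replicate 2 was. The reverse counts were 5754 and 20573. Of MEF-specific regions near Col1a2, 0.5 ± 0.707 (SD, n = 2) of 13 were open in iPS cells, and of those near Hoxb5, 4.5 ± 2.12 of 17.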

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

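The tests of mislabelled day 0 samples, of separately made lists and of other splits of the samples were chosen only after the result was seen.

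In the only group of 4 samples, GFP-negative cells of day 3, 1 sample lay far from the rest. OSK-D3-GFP-neg replicate 1 had 66.9% of always-open regions open, where the highest of its group had 89.0%, and its gap to the nearest other sample was 0.936 of the group's range and above Dixon's 95% critical value. It also listed 204718 regions, with a gap of 0.835 of the range. Chance alone exceeds the critical value in about 1 in 20 groups, and 4 measures were checked in this group. Groups of 2 samples were not checked in this way. Among them, OSK-D3-GFP-pos replicate 1 had 65.4% of always-open regions open. The low value was thus not confined to 1 sorted sample of day 3, and its cause was not tested.

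At day 0, OSK samples had already opened regions that S opens at day 1. The lowest of the 6 day 0 samples had 74.0% of the regions gained with S open, while the 2 MEF samples had 17.6 and 11.6% and the DsRed samples of day 1 had 2.81 and 3.46%. For the OSK-D0 samples, longer lists are argued against, since these regions were open more often than other regions open in as many day 1 samples, by 30.4 points in the sample with the smaller difference; in the OSK-cJun-D0 samples the differences were 22.6 and 13.6 points, and a part played by list length stays open there. Day 1 samples with all of OSK carrying a day 0 label are also argued against: the lowest day 0 sample had 60.4% of MEF-specific regions open, 16.7 points above the highest of the 6 day 1 samples with all of OSK at 43.7%. A candidate explanation that stays open is that the factors had acted before the day 0 sample was taken, whose time after infection the labels do not state. The values above go with it. So does the Klf4 exon region that tracked K among the day 1 factor groups. It was open in 2 of 2 samples of OSK-D0, OSK-DR-D0 and OSK-cJun-D0, though also in 1 of 2 MEF samples.

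The 10 GFP-sorted lists held 67268 catalogue regions found in no unsorted list, 8.86 to 17.7% of the catalogue regions of a list. Of these, 1414 were in at least 8 sorted lists and no other, while the highest of 100 random sets of 10 unsorted lists (from 5 groups) gave 16. For these 1414, it is argued against that sorted cells open regions which other cells keep closed. Of them, 90.7% lay within 400 bp of a region open in at least 10 unsorted lists, against 9.42% of other regions, a ratio of 9.63. The rest of the 67268 were not tested in this way, so their source stays open. A candidate explanation is that the lists of sorted cells were made in a separate run. Tests on sorted samples were therefore made only among them.

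Regions more open with cJun and with the Sap30 hairpins held many AP-1 sequences, though only 34.2 and 33.4% of them were MEF-specific, and 29.4 and 28.5% were open in no MEF and no ESC sample. Of MEF-specific regions more open with cJun, 57.9% held AP-1, 27.6 points above those closed in both arms. With the Sap30 hairpins on day 7 the share was 56.2%, 25.2 points above. These differences do not decide whether MEF-specific regions were held back in general, without regard to sequence. In OSK the AP-1 share varied with closing day, from 30.6% from day 0 to 47.9% from day 3, so a delay alone could give part of them. The lists of both comparisons shared 962 regions, 7.65 times the 126 of independent lists, and among MEF-specific regions 404, or 2.83 times. A hypothesis that stays open is that both treatments slow the closing of the same late-closing MEF-specific regions, although no closing day of the OSK course had an AP-1 share above 47.9%. Both comparisons have different controls and the hairpin samples have no replicates, so a shared cause may not be inferred from the overlap.

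For the region counts, chance assignment of samples can be excluded at the level of 1 in 100 splits, the real one included. The real and highest other counts were 1704 and 849 for O, 13713 and 7223 for S, 4513 and 1715 for K, and 7044 and 4725 for cJun. In the cJun splits the median was 1351 regions, so a part of the cJun counts is of the size that splits without the contrast give.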

How the results depend on the processing

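The settings without day 7, without 2 sorted samples, with classes also held in DsRed, scaled with the replicate block, with gene order rotated, with other gene windows and with regions open in as many day 1 samples, and the tests of gene lists on the day 1 and Sap30 region sets, were chosen only after the result was seen; the others were fixed before the data were examined.

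The lists give presence only, so a weakly open region and a shallow library look alike, and depth limits every percentage to an unknown degree. A stricter threshold by score or width and equal numbers of top regions could not be run, since every score is 0 and every listed region is 700 bp wide. Asking for 50% overlap, tiling the genome and keeping regions found in 1 list changed no call on the percentages. Of 179 alternatives to the 51 motif results that passed, 148 kept direction and threshold, 27 kept the direction only and 4 reversed. Against regions open in as many day 1 samples, AP-1 log2 odds ratios were -0.43 with S and -0.44 with K, and matched on GC content OCT was -0.23 and OCT-SOX -0.040 with S. Gene order rotated left 3 gene list results passing of 5 in the 78 tests fixed beforehand, and none of the 4 that passed in the 143 tests added on day 1 and Sap30 region sets (adjusted permutation p from 0.320 to 0.870). The cause was not tested for any change below unless stated.

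With classes that include iPS cells, the cJun difference in ESC-specific regions was -8.42 (exact permutation p = 0.0463), and the mean Sap30 differences were -9.94 and 7.63 for ESC- and MEF-specific regions. Scaled by always-open regions, O gave -4.73 for MEF-specific regions (adjusted exact permutation p = 0.0401), cJun -7.98 for ESC-specific (exact permutation p = 0.0278), GFP 10.3 (exact permutation p = 0.0333) and Sap30 8.13 for MEF-specific regions. With days 0, 1, 3 and 7, cJun gave -5.95 for ESC-specific regions (exact permutation p = 0.0262). Without day 7, it gave 10.3 for MEF-specific regions (exact permutation p = 0.0556), and 17578 regions more and 14217 less open, where fewer samples make the rule easier to meet. Without the 2 sorted samples of lowest always-open percent, GFP gave 10.0 for ESC-specific regions (exact permutation p = 0.0417). With classes also held in DsRed, cJun gave -6.97 for ESC-specific regions (exact permutation p = 0.0463) and Sap30 11.3 for MEF-specific. With every sample against none, which is stricter by construction, regions gained and lost were 314 and 13 for O, 4130 and 561 for S and 655 and 163 for K, and with cJun 527 were more and 120 less open.

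Replicate numbers were checked for pairing at single regions. There the correlation between the differences of replicates 1 and 2 in groups that would share a pairing ran from -0.0718 to 0.112. This does not rule out a shared shift in the percentages. Replicate 2 had more ESC-specific regions open than replicate 1 on every OSK and OSK-cJun day, and on every OSK-DR day but day 3. In MEF-specific regions the direction differed between OSK days. Whether replicate numbers pair the samples therefore stays open. A block on the replicate number left the ESC-specific cJun difference at -7.02 (exact permutation p = 0.0313), a change of call, and at -7.98 when also scaled (exact permutation p = 0.0313), and gave r = 0.953 and -0.822 for ESC- and MEF-specific regions with day. Counting a change within each number gave 3963 regions gained and 1515 lost for O, 17238 and 8745 for S, 7620 and 4550 for K, and 15417 more and 8549 less open with cJun.

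Leaving out each sample in turn gave these ranges. For ESC-specific and then MEF-specific regions they were 0.762 to 0.878 and -0.857 to -0.784 for r with day, 2.79 to 4.45 and -5.71 to -3.05 for O, 5.32 to 7.46 and -12.5 to -7.97 for S, 6.00 to 7.88 and -12.7 to -8.35 for K, -10.0 to -4.00 and 7.58 to 12.3 for cJun, 4.45 to 10.4 and -4.10 to 0.0194 for GFP, -19.6 to -6.22 and 4.90 to 25.9 for mES-OSK, -7.98 to -6.19 and 5.13 to 6.75 for Sap30 (only MEF and ESC samples left out, since the hairpin samples have no replicates), and 59.7 to 89.5% and 11.9 to 17.7% open in iPS cells. Regions gained and lost ran from 1588 to 2283 and 258 to 439 for O, 10245 to 13496 and 3927 to 5431 for S, and 3450 to 4929 and 1542 to 2140 for K. With cJun they ran from 4990 to 9545 more and 2910 to 5379 less open, and iPS-only and ESC-only regions from 19837 to 64293 and 5754 to 20573. Leaving out a sample eases the rules behind these region counts, so none of them can fall below the full count. Calls changed without OSK-cJun-D7 replicate 2 and without OSK-DR-D7 replicate 1 (cJun, MEF-specific, 8.26 and 8.24), without OSK-cJun-D1 replicate 2 and OSK-DR-D7 replicate 1 (cJun, ESC-specific, -7.98 and -10.0), without K-D1 replicate 1 (O, MEF-specific, -5.71) and without OSK-D3-GFP-pos replicate 1 (GFP, ESC-specific, 10.4, and MEF-specific, 0.0194).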

Other observations

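The region sets below were chosen only after the result was seen, and differences between the shares below were not tested.

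Many regions open during reprogramming were open in neither MEF nor ESC samples. They made up 23.8% of the regions open in both OSK samples on day 0, 32.2% on day 1 (35860 of 111436), 22.8% on day 3, 26.7% on day 5 and 18.2% on day 7 (14264 of 78457), beside 9.07% with DsRed and 9.54% in iPS cells. The 12773 of them that both OSK samples had open on day 1 and on day 3 were open at 43.5 and 49.4% in the S samples of day 1, 15.9 and 19.9% in the K samples, 17.2 and 21.5% in the O samples and 10.4 and 11.1% in the DsRed samples. In OSK samples of day 7 they were open at 50.2 and 67.0%, and in iPS cells at 12.8 and 14.8%. The SOX sequence was present in 18.9% of these 12773 (95% interval 18.3 to 19.6), KLF in 6.87%, OCT in 6.62% and AP-1 in 16.4%.

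Sequence content also varied with the day of change. The AP-1 sequence was present in 30.6% of MEF-specific regions closed from day 0, 37.1% from day 1, 47.9% from day 3, 43.2% from day 5 and 36.6% on day 7, and in 34.6% of those not closed in both samples of day 7. The earliest of these sets may include regions that DsRed samples did not list either. The SOX sequence was present in 27.2% of ESC-specific regions open from day 0, 23.1% from day 1, 21.2% from day 3, 17.4% from day 5 and 18.0% on day 7, and in 14.7% of the rest.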
